A study of Homo sapiens with 4 samples.

How the data were processed

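RNA of SKOV3 cells, a human ovarian cancer line, was measured on 4 one-colour (Cy3) Agilent arrays, 2 of control cells and 2 of cells in which the RNA-binding protein gene RBMS3 had been knocked out. The groups and replicate numbers were taken from the sample titles. The series' design text describes independent experiments, so the spread between the 2 arrays of a group is taken as a spread between experiments. The labels give neither the guide or edited part of RBMS3 nor what the control cells received.

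Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.1. Their spot signals are linear intensities, background-subtracted and detrended within each array and not normalized between arrays, per the file headers. Probe coordinates are those of hg19, per the file headers. The deposited value table holds log2 values with the same quartiles in all 4 columns, and on comparison its columns matched log2 intensities after quantile normalization. The column medians were 3.60 in each of the 4 columns, so scale and centring were found from the data. Both control columns correlated with their own scanner files at 1.00 after that normalization. The columns named for RBMS3 KO replicates 1 and 2 matched the scanner files in the opposite order: the column of replicate 1 correlated at 1.00 with the scanner file of replicate 2 and at 0.985 with its own. This does not touch the group comparison, but the order of the 2 RBMS3 KO arrays is not settled. Replicate numbers here are those of the scanner files.

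Each array held 62976 spots, of which 2075 were control spots and were left out. The remaining 60901 spots belonged to 58201 different probes. Spots carrying an outlier flag were left out, repeated spots of a probe were averaged on the log2 scale, and 6 probes with no usable spot on some array were dropped. The main values were log2 processed signals minus each array's 75th percentile over non-control probes. Probes were kept where the scanner software called them well above background on both arrays of at least 1 group, which left 25078 probes, 22050 of them well above background on all 4 arrays. No spot was saturated. Signal over background and the number of arrays limit the precision. Under 50% of the probes were well above background on each array, so a percentile over the probes well above background on all arrays was added as an alternative after seeing the data.

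Probe names were updated through a RefSeq gene table of assembly GRCh38.p14, used for names alone. By accession 31101 probes were matched, by symbol 3366 and by a synonym of a single gene 496, and 23232 kept the name in the file. A gene was represented by its brightest kept probe, giving 19795 genes or unnamed features. Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, group as the term, two-sided) on all kept probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Data were read with the data.table package, version 1.17.8, and drawn with matplotlib 3.10.9. With 2 arrays against 2, an exact permutation test cannot give a p below 0.333, so limma, which pools the spread over probes, was the test.

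Before the data were examined, 38 lists holding 809 distinct genes were fixed, and limma's camera with a preset correlation of 0.01 between genes was run on those with at least 3 detected members. Camera with an estimated correlation and fry stood beside it. The rule for named genes was also fixed then. It took RBMS3, the 12 largest called changes per direction or, with under 5 calls, the 10 genes per direction with the smallest unadjusted p, up to 6 genes per direction measured in 1 group alone, 9 genes of interest from knowledge of the study, and the leading members of each list described. Genes without an ordinary symbol were passed over, and a few results that the rule selects are not reported here. For a probe not well above background in 1 group, the fold is a bound. It is the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

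The test was checked on simulated arrays drawn from the real probe means over 19795 genes, with 200 genes changed per run over 10 runs. With the spread fitted to all 4 arrays, limma recovered 0% of the 2-fold, 0% of the 4-fold, 7.0% of the 8-fold and 33.8% of the 16-fold changes in the comparison of RBMS3 KO with control, with 1.3 false calls per run. With the spread of the RBMS3 KO pair alone it recovered 4.4%, 85.2%, 99.0% and 99.8%, with 5.2 false calls per run. Of 30 simulated lists shifted by 0.5 on the log2 scale at the spread of all 4 arrays, camera called 26 with the preset correlation and 0 with an estimated correlation, and fry called 2. Camera with the preset correlation called 1 of 340 unshifted lists. Simulated genes varied independently, which real genes of a list do not, so these counts do not carry over to lists whose members vary together.

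The alternatives were normexp background correction with an offset of 50, quantile and median normalization, the value table, other detection filters, a trended robust prior, the replicate number as a block, means over probes, each array left out in turn, other thresholds and other set tests. Cyclic loess was added after seeing the data. All 4 arrays lay on 1 slide and came from 1 scan, so slide and scan were no batches.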

Results

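The series asks how the transcriptome of SKOV3 cells differs when RBMS3 is missing. RBMS3 encodes an RNA-binding protein, and the study places it among regulators of Wnt/beta-catenin signalling through miR-126-5p. Expression was measured on 4 whole-transcriptome arrays, 2 of control cells and 2 of RBMS3 KO cells, and values below are log2 signals relative to each array's 75th percentile. That percentile lay at a signal of 196.9 on control replicate 1, 74.0 on control replicate 2, 137.4 on RBMS3 KO replicate 1 and 127.0 on RBMS3 KO replicate 2. The shares of probes well above background were 47.6%, 40.3%, 44.4% and 44.3% in the same order. Over the 22050 probes well above background on all arrays, the 2 RBMS3 KO arrays correlated at 0.988 across probes, and 2.63% of the probes lay over 2-fold apart. The 2 control arrays correlated at 0.940, and 25.9% of the probes lay over 2-fold apart. Control replicate 1 correlated at 0.990 and 0.984 with the RBMS3 KO arrays, so it stood closer to them than to control replicate 2.

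RBMS3 itself was weakly expressed. Its probe A_23_P10995 spans positions 29925698 to 29938927 of chromosome 3 in hg19, a span longer than the probe itself. Its signals were 69.7 and 20.1 on the control arrays and 31.7 and 29.1 on the RBMS3 KO arrays. Relative to each array's 75th percentile this was -1.69 ± 0.27 (SD, n = 2) in control and -2.12 ± 0.01 (SD, n = 2) in RBMS3 KO cells. The log2 fold change of -0.43 had a standard error of 0.37 and a 95% interval from -1.33 to 0.46, and it did not pass (limma adjusted p = 1.00). It was -0.20 for RBMS3 with normexp background correction and -0.24 without control replicate 1. Because the edited part of the gene is not given in the sources used here, and an edited gene may still be transcribed, the probe need not report the knockout. The antisense transcript RBMS3-AS3 had a log2 fold change of -1.37 with a standard error of 0.60 and did not pass either (limma adjusted p = 1.00). The value for RBMS3-AS3 was -0.73 without control replicate 2, -2.01 without control replicate 1 and -0.81 without RBMS3 KO replicate 2. Among the paralogs, RBMS1 stood at -0.26 ± 0.36 (SE) and RBMS2 at -0.05 ± 0.37 (SE), and 1 of the 3 RBMS1 probes had the opposite sign at 0.05. The RBMS2 value was 0.17 without control replicate 2.

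As lists, DNA replication and mitosis genes had lower signals in RBMS3 KO than in control cells, and replication-dependent histone genes and genes of the unfolded protein response and the ATF4 pathway had higher signals, by camera with a preset correlation. These calls were lost with an estimated correlation (camera adjusted p = 0.964 for each) and fry called 0 lists, and the call of the unfolded protein response was lost without control replicate 2 (camera adjusted p = 0.0664). On simulated arrays the same tests called 0 and 2 of 30 shifted lists, but simulated genes varied independently. Those counts do not carry over to real lists, so they do not show what a lost call means. Grouping the arrays by replicate number called 11 lists, against 9 for the real groups. No single gene passed. Limma called 0 of the 19795 genes at an adjusted p under 0.05, with 222 genes at an unadjusted p under 0.05 (92 higher and 130 lower in RBMS3 KO cells, 1.12% against 5% expected by chance) and 0 called by limma with a trended robust prior. The smallest adjusted p was 1.00. The groups did not overlap for 2840 genes that were higher and 1876 that were lower in RBMS3 KO cells, 23.8% of the genes, where chance gives 33.3%. The count rested on the control arrays: without control replicate 1, so against control replicate 2 alone, limma called 3053 genes (1666 higher, 1387 lower), and without control replicate 2 it called 1.

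Among genes with the smallest unadjusted p, the centriole protein gene CEP135 was at -0.79 ± 0.09 (SD, n = 2) in control and -2.35 ± 0.19 (SD, n = 2) in RBMS3 KO cells, a log2 fold change of -1.56 ± 0.36 (SE). POLK and POLQ, which encode translesion and end-joining DNA polymerases, had log2 fold changes of -1.56 ± 0.37 (SE) and -1.71 ± 0.49 (SE). The values were -1.48 for the mitotic kinesin KIF14, -1.59 for the cohesin acetyltransferase ESCO2 and -1.502 for the transcription factor MYB. DDX60L stood at -2.00, CRYBG3 at -1.17 and PIK3C2A, a lipid kinase, at -1.13. In the other direction GLI4, a zinc finger gene, was at 5.69 ± 0.51 (SD, n = 2) in control and 7.19 ± 0.00 (SD, n = 2) in RBMS3 KO cells, a log2 fold change of 1.498 ± 0.41 (SE). GDF15, a stress-induced cytokine, stood at 1.61 ± 0.52 (SE), the receptor gene IL21R at 1.60, the calcium-binding protein gene S100P at 1.27, the kinase gene HIPK2 at 1.26 and the mitochondrially encoded ND1 at 1.16. The remaining values were 1.32 for TLCD2, 2.35 for SLC22A11, an organic anion transporter, 1.204 for GTPBP2 and 1.00 for RNF222. The second SLC22A11 probe had the opposite sign. With normexp background correction, whose offset shrinks the folds of dim probes, the values were -0.68 for CEP135, -0.98 for POLK, -0.67 for ESCO2, -0.54 for MYB, -1.03 for DDX60L, -0.51 for CRYBG3, 0.66 for S100P and 1.55 for SLC22A11, and the value for POLQ was smaller as well. Without control replicate 2, DDX60L stood at -1.22 and SLC22A11 at 1.099, GDF15 was at 1.05 without RBMS3 KO replicate 2, and HIPK2 was at 0.76 as the mean of its probes. None of these genes passed (limma adjusted p = 1.00 for each). Many of the named genes passed against control replicate 2 alone, so without control replicate 1. That fit holds a lone control array, with the spread taken from the RBMS3 KO pair. The genes were picked largely by their p on these same arrays, so those calls add no support.

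**Figure D1:**
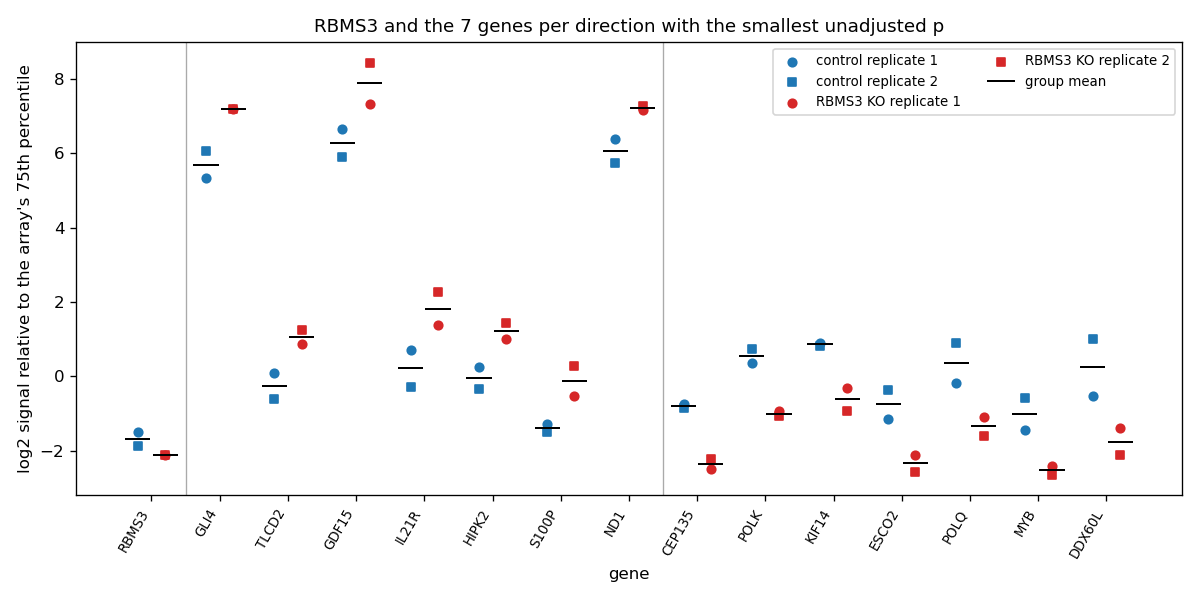
The vertical axis gives the log2 signal relative to the array's 75th percentile for RBMS3 and for the 7 genes per direction with the smallest unadjusted p, with 1 point per array and a bar at each group's mean. RBMS3 lay at -1.498 and -1.88 on the control arrays and at -2.12 and -2.13 on the RBMS3 KO arrays; none of these genes passed limma's adjusted threshold.

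Of 38 lists, 37 had at least 3 detected members, and camera with the preset correlation called 9 of them, 2 higher and 7 lower in RBMS3 KO cells. Each of the 9 calls was lost with an estimated correlation (adjusted p = 0.964 for every called list), and fry called 0 lists (lowest adjusted p = 0.998 by direction and 0.951 for mixed changes). Of 30 simulated lists shifted by 0.5 at the spread of all 4 arrays, these tests called 0 and 2. At the spread of the RBMS3 KO pair alone they called 0 and 8. Simulated genes varied independently, so these counts do not show whether the tests could keep a call on members that vary together. The 9 calls rest on the preset correlation. The correlation estimated between members lay above the preset 0.01 in each of the 9, from 0.0386 for G2/M and mitosis and 0.291 for G1/S to 0.632 for MHC class I and 0.852 for interferon-stimulated genes. No member of any list passed over all genes tested or adjusted over the list alone (0 calls by limma in both cases), and the counts below are of members at an unadjusted p under 0.05.

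DNA replication and mitosis genes were lower as groups. Of 34 measured genes of G1/S and DNA replication, 33 had lower means in RBMS3 KO cells, the median log2 fold change was -0.61 (1.52-fold lower), and 18 were below both control arrays on both RBMS3 KO arrays (camera adjusted p = 7.45e-14, and adjusted p = 0.964 with an estimated correlation). Of its members 3 were lower at an unadjusted p under 0.05, and the leading 2 were E2F8, a transcription factor of the cell cycle that was not well above background in RBMS3 KO cells and was at least 1.85-fold lower there, and CCNE2, the S phase cyclin E2, at -1.66 ± 0.52 (SE). For the G2/M and mitosis list, 30 of 38 members were lower, the median was -0.32, and 2 members were lower at that p (camera adjusted p = 1.18e-06, and adjusted p = 0.964 with an estimated correlation). They were CENPF, a kinetochore protein gene, at -1.22 ± 0.47 (SE) and TOP2A, topoisomerase 2 alpha, at -0.93 ± 0.38 (SE). Both lists were lower against each control array: the medians were -0.27 and -0.89 for G1/S against control replicates 1 and 2, and -0.16 and -0.46 for G2/M.

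Replication-dependent histone genes went the other way. Of 16 measured, 15 had higher means in RBMS3 KO cells, 13 were above both control arrays on both RBMS3 KO arrays, and the median log2 fold change was 0.58, or 1.49-fold (camera adjusted p = 1.18e-06, and adjusted p = 0.964 with an estimated correlation). H2BC7 stood at 1.21 ± 0.48 (SE) and H2AC8 at 0.66 ± 0.36 (SE). The medians against control replicates 1 and 2 were 0.37 and 0.77. These 3 lists were called without any 1 of the 4 arrays and under every normalization and filter tried.

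Genes of the unfolded protein response and ATF4 pathway were higher as a group, with 22 of 30 members higher, 12 of them above both control arrays on both RBMS3 KO arrays, and a median of 0.70, or 1.62-fold (camera adjusted p = 1.25e-06, and adjusted p = 0.964 with an estimated correlation). SLC3A2, a subunit of amino acid transporters, was at 1.07 ± 0.43 (SE) and DDIT4, a stress-induced inhibitor of mTORC1, at 1.21 ± 0.54 (SE). The medians against control replicates 1 and 2 were 0.36 and 0.90. Relative to each gene's mean over the 4 arrays, the medians were -0.06 and -0.59 on control replicates 1 and 2. On RBMS3 KO replicates 1 and 2 they were 0.0002 and 0.53, so RBMS3 KO replicate 1 lay close to control replicate 1. Without control replicate 2 the list no longer passed (camera adjusted p = 0.0664), and RBMS3 KO replicate 2 lay above RBMS3 KO replicate 1 by a median of 0.53.

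Interferon-stimulated genes had the largest shift of the 9 lists, and most of it came from control replicate 2. On both RBMS3 KO arrays 15 of 32 measured members were below both control arrays, as were 1876 of all 19795 genes. These shares are not alike, since 31 of 32 members were higher on control replicate 2 than on control replicate 1. For this list the count therefore mostly compares control replicate 1 with the RBMS3 KO arrays, and it shows no shift apart from control replicate 2. All 32 measured members had lower means in RBMS3 KO cells, the median was -1.56 (2.94-fold lower), 5 were lower at an unadjusted p under 0.05 (camera adjusted p = 1.65e-16, and adjusted p = 0.964 with an estimated correlation). DDX60 stood at -1.60 ± 0.59 (SE) and PARP9 at -1.03 ± 0.41 (SE). The median was -0.11 against control replicate 1 and -2.90 against control replicate 2, and without control replicate 2 the list did not pass (camera adjusted p = 0.0847). RSAD2, an antiviral enzyme gene, was at -1.98 on control replicate 1, 4.33 on control replicate 2, and -2.43 and -1.76 on the RBMS3 KO arrays. The ubiquitin-like ISG15 was at 6.82, 11.31, 7.31 and 7.52 on the same arrays.

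Antigen presentation, inflammatory and heat shock genes followed the same arrays. The list of MHC class I and antigen presentation had all 14 measured members lower and a median of -0.47 (camera adjusted p = 0.000395, and adjusted p = 0.964 with an estimated correlation), with PSMB9, an immunoproteasome subunit, at -0.92 ± 0.69 (SE) and B2M, the light chain of class I molecules, at -0.97 ± 0.74 (SE). The NF-kB and inflammatory list had 10 of 15 members lower and a median of -0.67 (camera adjusted p = 0.0121, and adjusted p = 0.964 with an estimated correlation), with TNFAIP2 at -1.05 ± 0.52 (SE) and BIRC3, an inhibitor of apoptosis, at -1.75 ± 0.99 (SE). The heat shock list had 12 of 14 members lower and a median of -0.36 (camera adjusted p = 0.0440, and adjusted p = 0.964 with an estimated correlation), with HSPA1B at -1.17 ± 0.86 (SE) and CRYAB, a small heat shock protein gene, at 0.48 ± 0.36 (SE). Against control replicate 1 the 3 medians had the opposite sign, at 0.16, 0.08 and 0.18, and against control replicate 2 they were -1.26, -1.32 and -0.99. Without control replicate 2 none of the 3 passed (camera adjusted p = 0.904, 0.752 and 0.548). The heat shock list was also lost without RBMS3 KO replicate 1 (camera adjusted p = 0.234), with no detection filter (0.0997) and with the mean of all probes of a gene (0.0577).

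**Figure D2:**
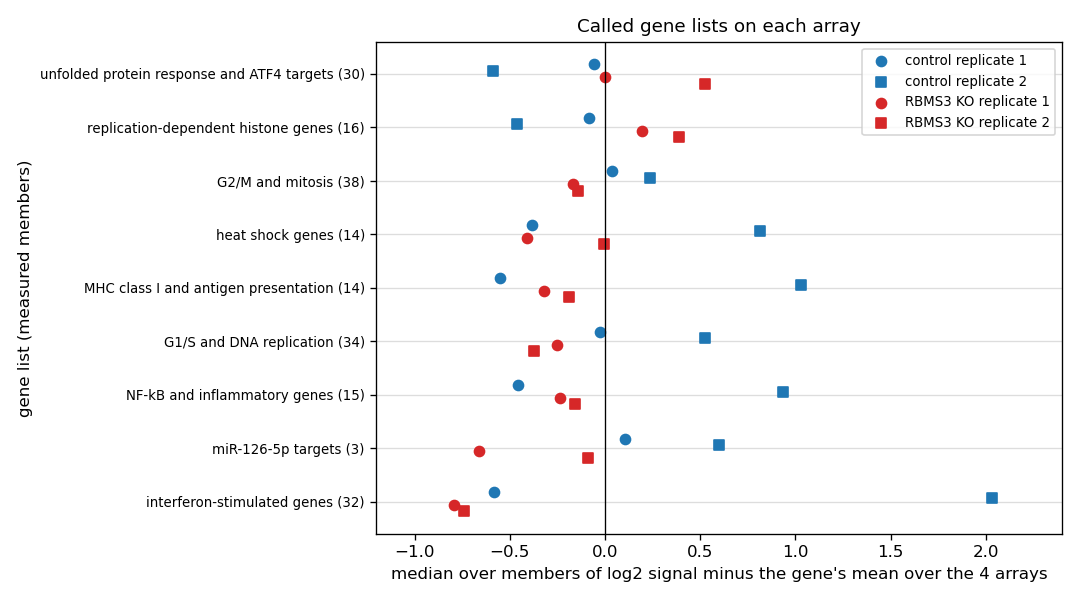
Each point gives, for 1 array, the median over a list's measured members of the log2 signal minus the gene's mean over the 4 arrays; circles are replicate 1, squares replicate 2, blue control and red RBMS3 KO. Interferon-stimulated genes lay at 2.03 on control replicate 2 and between -0.79 and -0.58 on the other arrays, while histone genes lay at 0.20 and 0.39 on the RBMS3 KO arrays and below 0 on both control arrays.

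The study's own axis, miR-126-5p targets that restrain beta-catenin, was represented by 4 genes taken from knowledge of the study, so their list is not independent evidence of its direction. The DKK3 probes were not well above background on any array. The other 3 had lower means in RBMS3 KO cells, with a median of -0.75 (camera adjusted p = 0.0277, and adjusted p = 0.964 with an estimated correlation), and none passed alone. The transcription factor genes BACH1 and NFAT5 were at -0.92 ± 0.43 (SE) and -0.75 ± 0.39 (SE), lower on both RBMS3 KO arrays than on both control arrays. AXIN1, a scaffold of the beta-catenin destruction complex, was at -0.10 ± 0.47 (SE) and stood at 0.45 without control replicate 2. The list did not pass without control replicate 1 (camera adjusted p = 0.162), without control replicate 2 (0.345), without RBMS3 KO replicate 1 (0.368) or with no detection filter (0.0644). Without control replicate 2, BACH1 stood at -0.56 and CTNNB1 at 0.03, while the second CTNNB1 probe stood at -0.19 (0.42 with all arrays). NFAT5 was at -0.47 without RBMS3 KO replicate 1. CTNNB1, which encodes beta-catenin, was at 0.41 ± 0.44 (SE). The coactivator gene CREBBP was at 1.25 ± 1.28 (SE) but was not well above background on control replicate 2, and without that array it stood at -0.86. EGFL7, the host gene of miR-126, was at 0.38 ± 0.35 (SE). None of these genes passed (limma adjusted p = 1.00 for each).

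Other Wnt groups did not pass in the comparison of all 4 arrays. Wnt/beta-catenin target genes had 12 of 20 members lower and a median of -0.24 (camera adjusted p = 0.270), with the growth factor gene VEGFA at 0.95 ± 0.45 (SE) and FGF18, below detection in RBMS3 KO cells, at least 2.30-fold lower there and at least 1.15-fold without control replicate 2 or 4.63-fold without control replicate 1. The 27 measured genes of the list Wnt ligands, receptors and beta-catenin cofactors had a median of -0.12 (camera adjusted p = 0.2502) and passed as lower without control replicate 2 (camera adjusted p = 0.000924) and without RBMS3 KO replicate 1 (0.0245). RBMS3 KO replicate 2 lay below RBMS3 KO replicate 1 by a median of 0.399 for this list. Their leading members were the receptor gene FZD3 at -0.85 ± 0.44 (SE) and the ligand gene WNT6 at -0.89 ± 0.50 (SE). The 15 Wnt inhibitors had a median of -0.00 (camera adjusted p = 0.803), with a mean just above 0, and their leading members were DKK4 at -0.49 ± 0.41 (SE) and CTNNBIP1 at 0.47 ± 0.59 (SE).

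For survival and drug response, the medians were -0.02 for anti-apoptotic genes, 0.04 for pro-apoptotic genes, 0.00 for drug efflux and platinum handling and -0.07 for excision and recombination repair, with camera adjusted p values of 0.650, 0.916, 0.746 and 0.517. For the drug handling list the mean was -0.08 and the test pointed down. The members with the smallest p were BIRC3 and BIRC2 (-0.46 ± 0.43, SE) among anti-apoptotic genes, and the death receptor gene TNFRSF10B (1.04 ± 0.51, SE) and BMF (-0.59 ± 0.36, SE) among pro-apoptotic genes. For drug handling they were the transporter genes ABCC3 (-1.74 ± 0.91, SE) and ABCC4 (0.73 ± 0.40, SE), and for repair BARD1, the partner of BRCA1 (-0.85 ± 0.39, SE), and ERCC2 (0.73 ± 0.41, SE). The p53 target genes had a median of 0.13 (camera adjusted p = 0.707), led by GDF15 and by PLK2 at -0.86 ± 0.39 (SE).

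Lists on cell state did not pass either. Medians were -0.04 for epithelial, 0.04 for mesenchymal, 0.17 for collagen and matrix, -0.11 for TGF-beta target and 0.02 for YAP/TAZ target genes, with camera adjusted p values from 0.650 to 0.916. The means of the mesenchymal and YAP/TAZ lists had the opposite sign, at -0.03 and -0.07. The leading members were the tight junction gene CLDN7 (1.19 ± 0.56, SE; well above background on 1 of 2 control arrays) and JUP (-0.69 ± 0.50, SE) among epithelial genes, and ZEB1, a repressor of epithelial genes (-0.79 ± 0.37, SE), and ACTA2 (0.55 ± 0.38, SE) among mesenchymal genes. BGN and TNC led the matrix genes at -1.51 ± 0.90 (SE) and -1.44 ± 0.88 (SE), BAMBI and ID2 the TGF-beta targets at -1.15 ± 0.56 (SE) and -0.80 ± 0.51 (SE), and ASAP1 and AMOTL2 the YAP/TAZ targets at -0.63 ± 0.37 (SE) and -0.56 ± 0.44 (SE). Stemness genes had a median of 0.05 with a mean of -0.02, angiogenesis factors 0.27, receptor tyrosine kinases and ligands 0.16, immediate-early genes -0.00 and the RBMS family with related RNA-binding proteins -0.05 (camera adjusted p from 0.707 to 0.790). Immediate-early genes passed as higher without control replicate 2 (camera adjusted p = 0.0474) and as lower without RBMS3 KO replicate 2 (0.0200). Leading members of these lists were LIN28B at -0.67 and POU5F1 at 0.57 for stemness, VEGFA and PDGFA (0.60) for angiogenesis, NRG1 at 0.62 and DDR2 at 0.80 for receptor kinases, ATF3 at 1.09 and SPRY1 at -0.81 for immediate-early genes, and DICER1 at -0.60 and RBM3 at 0.66 for RNA-binding proteins.

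Among metabolic lists, medians were -0.07 for hypoxia and glycolysis, 0.18 for cholesterol synthesis, 0.05 for fatty acid synthesis, 0.14 for oxidative phosphorylation, 0.12 for ribosomal proteins and -0.08 for NRF2 targets (camera adjusted p from 0.2502 to 0.827). The lists cytosolic ribosomal proteins and oxidative phosphorylation, nuclear-encoded passed as higher with normexp background correction (camera adjusted p = 0.000240 and 0.0124). With 1 array left out, ribosomal proteins passed as higher without control replicate 2 (camera adjusted p = 0.000924), fatty acid synthesis as higher without RBMS3 KO replicate 1 (0.0249) and NRF2 targets as lower without RBMS3 KO replicate 2 (0.0199). Cholesterol synthesis passed as higher without control replicate 2 (camera adjusted p = 0.000454) or RBMS3 KO replicate 1 (4.12e-05) and as lower without RBMS3 KO replicate 2 (3.86e-05). The glucose transporter gene SLC2A3 was at 1.57 ± 0.59 (SE) and with VEGFA led the hypoxia list. TM7SF2 and SREBF2 led cholesterol synthesis at 0.65 and 0.64, ELOVL6 and FADS1 fatty acid synthesis at -0.76 and 1.02, UQCRC1 and ATP5F1B oxidative phosphorylation at 0.49 and 0.45, RPLP0 and RPL3 the ribosomal proteins at 0.49 and 0.49, and ABCC3 and SRXN1 (0.39) the NRF2 targets.

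Of the listed markers of other cell types, 6 of 10 were measured for fibroblasts, 7 of 12 for leukocytes, 3 of 10 for endothelium and 1 of 8 for mesothelium. The medians were 0.00, 0.22, -0.05 and -0.09, and the 3 lists that could be tested did not pass (camera adjusted p = 0.916 for each). Fibroblast markers passed as lower without control replicate 2 (camera adjusted p = 0.0370). The 4 measured ovarian tumour line markers had a median of 0.05 (camera adjusted p = 0.982). For leukocytes, endothelium and the ovarian markers the median, mean and test differed in sign.

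Of the 19795 genes, some were measured in 1 group alone, 74 in RBMS3 KO cells and 182 in control cells. The share of probes well above background differed by array, from 40.3% to 47.6%, so these counts alone do not show expression lost or gained. The long non-coding RNA LINC02909 was at least 3.06-fold higher in control cells and LRRK2, a kinase gene, at least 1.77-fold, with ACVR1C, an activin receptor, at 1.88-fold or more. The bounds for RIBC2, CCDST and NXNL1 were at least 1.35-fold, 2.64-fold and 1.28-fold. RIBC2 and NXNL1 rested on control replicate 2, without which their bounds were 0.816 and 0.735, so that they no longer bounded the direction. In the other direction the bounds were at least 1.84-fold for the metalloprotease gene ADAMTS17, 1.56-fold for ST7-AS2, 1.56-fold for the cytokine IL26, 1.19-fold for OR6C74 and 1.07-fold for ATP2A1. Without control replicate 1 the bounds of OR6C74 and ATP2A1 were 0.817 and 0.737, also under 1. The bound of ADAMTS17 was 1.18-fold without RBMS3 KO replicate 2 and 2.87-fold without RBMS3 KO replicate 1. With normexp background correction the log2 fold changes were smaller, at -0.77 for LINC02909, 0.56 for ADAMTS17 and 0.19 for ATP2A1. None passed (limma adjusted p = 1.00 for each).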

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

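The percentile over detected probes and cyclic loess were chosen after seeing the data. Limma called 0 genes under every normalization, filter and prior tried on all 4 arrays without a block, and with a 2-fold threshold, and 222 genes stood at an unadjusted p under 0.05. With the replicate number as a block it called 18 genes (8 higher, 10 lower), 3 of them named, and camera 8 lists; the numbers are only shared, deviations of same-numbered arrays correlated at 0.249, the order of the RBMS3 KO arrays is unsettled, and apart from the lost miR-126-5p list the block changed no list call. Leaving out 1 array at a time, with the lone array assumed to vary like the other group, gave 0 to 3053 genes, 8 to 12 lists and RBMS3 at -0.62 to -0.24; over all alternatives RBMS3 stayed below 0 and did not pass. Camera with an estimated correlation and fry called 0 lists; elsewhere 7 to 11 were called. With normexp AXIN1 and RBMS2 turned to 0.0162 and 0.00729. Leaving out 1 array, they ranged from -0.64 to 0.45 and from -0.27 to 0.17, and CREBBP from -0.86 to 3.36. Camera adjusted p then ranged from 0.000358 to 0.752 for NF-kB and inflammatory genes, 0.000124 to 0.904 for MHC class I and antigen presentation, 0.00389 to 0.548 for heat shock genes, 0.0200 to 0.517 for MAPK feedback and immediate-early genes, 0.0370 to 0.978 for fibroblast markers and 3.86e-05 to 0.341 for cholesterol synthesis and uptake, each with both directions; control replicate 2 turned the first 5, and without RBMS3 KO replicate 2 cholesterol genes passed as lower. Fewer arrays enter these fits, and the cause of these moves was not tested. Of all gene and list values compared, 557 of 587 and 619 of 663 kept their side of the threshold. Median scaling moved the median of all probes to 0.10. Slide blocking and a saturation filter were not run, since there was 1 slide and no saturated spot. Signal over background limits RBMS3, DKK3 and CREBBP.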

Other observations

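All tests in this part were chosen after the result was seen, except the count over splits of the arrays. Genes also differed between arrays of the same group. Among genes well above background on all 4 arrays, the 15 genes furthest above control replicate 1 on control replicate 2, picked by their size, were led by IFNL2, an interferon lambda, at -1.48 and 5.75, and held RSAD2, IFI6, IFI27, IFITM1, OASL and the chemokine gene CCL3, at 2.03 and 6.997. The rest of these 15 were KCNN4, CSAG1, SFN, CSAG4, LGALS9C, CCL3L3, PABPN1L and IL4I1. The 15 genes furthest below were led by the cytokine receptor gene IL20RB, at 3.04 and -1.97. They held the stress gene NUPR1, at 6.12 and 2.38, and also SH3PXD2A, HOXC4 and HUWE1. On the RBMS3 KO arrays IFNL2 was at -1.05 and -1.01 and IL20RB at 2.96 and 2.396.

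By the replicate numbers of the scanner files, genes of cholesterol synthesis were higher on replicate 2 than on replicate 1 in both groups. The value table gives the RBMS3 KO arrays in the opposite order, under which the direction within RBMS3 KO cells would turn. HMGCS1, an early enzyme of the pathway, was at 1.71 and 5.46 on the control arrays and at 1.49 and 4.003 on the RBMS3 KO arrays. The list's median difference was 1.48 between the control arrays and 1.13 between the RBMS3 KO arrays, each above all of 10000 random lists matched on signal. Random lists drew genes independently, and the correlation estimated between members of this list was 0.496. Their range does not measure how far a list of genes that vary together moves between 2 arrays. NRF2 target genes, which answer oxidative stress, differed by 0.83 and 0.45 in the same order, with HMOX1 at 5.84 and 9.02, and at 7.08 and 9.30. The difference was not particular to these lists. Immediate-early genes differed by 0.89 and 0.40 and heat shock genes by 1.27 and 0.38. Other lists did not share it, such as the unfolded protein response and ATF4 targets at -0.62 and 0.53.

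Interferon-stimulated genes were high on control replicate 2 alone, with 31 of 32 members above control replicate 1 and a median difference of 2.43. A dim array or its scaling is argued against. Scaling by a constant per array cannot move a list against random lists, so only normexp, quantile normalization and cyclic loess test this. Under these the medians were 1.85, 2.34 and 2.24, above all random lists in each. The genes of random lists were drawn independently, so their range leaves out the spread of members that vary together. Leukocytes in the sample stay open: all 7 detected markers were higher on control replicate 2, by a median of 0.698 (CD3E by 2.94), but lay near the floor and within the range of matched random lists, and CD2, CSF1R and MS4A1 were not well above background. Position on the slide cannot be told apart from the array, as control replicate 2 was the only array in its row (1 array), and the design names no biological difference between control arrays, so none was tested.

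Control replicate 1 lay nearer to both RBMS3 KO arrays than to control replicate 2. A difference in scaling is argued against. With quantile normalization, cyclic loess or normexp the correlation of the control arrays reached at most 0.948. That of control replicate 1 with an RBMS3 KO array was at least 0.984. Rescaling cannot remove noise of a dim array, so brightness itself stays open. Control replicate 2 was the dimmest array, and its correlations fell as the other array was brighter. They were 0.958 with RBMS3 KO replicate 2, 0.951 with RBMS3 KO replicate 1 and 0.940 with control replicate 1. The RBMS3 KO arrays, nearest in brightness, correlated at 0.988, below the 0.990 of control replicate 1 with RBMS3 KO replicate 1. A swap with an RBMS3 KO array stays open: control replicate 2, which stands apart from all, correlated at up to 0.958 with an RBMS3 KO array and at 0.940 with control replicate 1. Knockout cells under the label of control replicate 1 also remain possible: RBMS3 stood 0.62 above the RBMS3 KO mean there, and 3.74% of 1364 equally bright probes stood as far above (18.2% as far above or below), but the edited part is unknown. The absence of RBMS3 having little effect on the arrays could also give this order and was not tested apart from these values.

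The difference in cholesterol genes between replicates was not removed by scaling, as the smallest median between the RBMS3 KO arrays over 6 normalizations was 1.02. A day or culture shared by arrays of the same number may account for it: deviations of same-numbered arrays correlated at 0.246 over probes outside the list. With 2 pairs, and the value table giving the RBMS3 KO arrays in the opposite order, this cannot be told apart from chance. No biological explanation was tested, because the design names none.

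Of the 3 splits of the 4 arrays into pairs, 2 gave at least 9 called lists, counting the real split, which gave 9. The others gave 11 and 5, with 11 for replicate 1 of each group against replicate 2 of each, where 1530 genes stood at an unadjusted p under 0.05 against 222 for the real split, and limma called 0 genes in both. With the value table's order of the RBMS3 KO arrays that split would be the crossed one, so it does not settle whether the number marks a shared day. A total of 3 splits is too few for a share under 0.05.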
